A study of Homo sapiens with 6 samples.

How the data were processed

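The deposited files were peak lists from ATAC-seq of HCT116 cells in which RAD21 carries an auxin-inducible degron, with 4 untreated libraries and 2 libraries of cells given 5-Ph-IAA. Per the labels' protocols, libraries were made with Tn5 transposase and sequenced on a NovaSeq X Plus. Per the submitters' processing notes, cutadapt, Bowtie2, SAMtools and MACS2 were used with the build hg38, and no versions, roles or settings were given there. Whether read ends were shifted for the Tn5 insertion, whether duplicates were removed and which mapping quality was required is not given in the sources used here. Each of these can move peak edges and numbers, and a mapping quality minimum removes reads that match several places of the build. Peaks were called per library, since each list carried the name of 1 library, so that a region missing from a list can be a region just under the caller's threshold.

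Per the narrowPeak format of the deposited lists, each peak had a start and an end, a summit position, a fold enrichment over the caller's local background (a ratio), -log10 of the p-value and of the q-value, and a score, which equalled 10 times -log10 q rounded down. These are the authors' own values for each peak and were used only to rank and filter peaks within a list. The smallest -log10 q was between 4 and 4.03 in the 6 lists, so the deposited lists stop near a q of 1e-04. A further deposited file, written with rtracklayer 1.58.0 per the file headers, held intervals without values. They were the 56763 peaks of untreated 1 that overlap a peak of untreated 2, listed once per overlap in 61779 lines, and were not used in any comparison, because untreated 1 and 2 overlap them fully by construction. Peaks of 5-Ph-IAA 1 and 2 overlapped 95% and 96.4% of them, and those of untreated 3 and 4 85.7% and 95.1%.

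Depth was read from the authors' values. The fold enrichment and the -log10 p of a summit together give the whole number of extended reads at the summit and the local background. These were recovered to within 0.002 of the deposited -log10 p for 99.99% of peaks in untreated 3 and 4. In the other libraries the share was 97.03% to 97.4%. The most common background is the genome-wide one, and the smallest peak width, 98, 74, 99 and 74 bp in untreated 1 to 4 and 87 and 74 bp in 5-Ph-IAA 1 and 2, is the extension length under the caller's default. Background pileup per kb of extension, an index of depth, was 5.31, 5.27, 4.04 and 5 in untreated 1 to 4 and 5.52 and 5.81 in 5-Ph-IAA 1 and 2. No read counts were used, so no count model was fitted, and single values carry no counting interval.

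Peaks on chromosomes 1 to 22, X and Y were kept, which left out 201 to 296 peaks per library on other sequences. Peaks of the 6 libraries that shared at least 1 bp were merged into 89455 regions, and a region was called in a library where it overlapped one of its peaks by at least 1 bp. Regions called in all 6 libraries were ranked within each library by their highest -log10 q, as percentiles over the same 45111 regions. Overlap of library pairs was measured as the Jaccard index of covered bases. Genes came from the RefSeq table of GRCh38.p14, with 20037 protein-coding genes and all 291 listed gene entries matched. It holds outermost gene bases without strand or transcripts, so the planned 1000 bp windows around transcript starts were replaced by 1000 bp either side of both gene ends. Peaks were placed at a gene end, inside a gene or outside genes by their summits and merged regions by their midpoints, while a gene or list member counted as open where a peak overlapped either window. The planned search for the CTCF motif needs a genome sequence and was not run, and motifs were not analysed here.

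The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Group differences in single values were tested with an exact two-sided permutation test over all 15 splits of the 6 libraries into 4 and 2, whose smallest possible p is 0.0667. Counts of regions open in one group alone, or whose ranks do not overlap between groups, were set beside the same counts under the other 14 splits. Gene lists were tested by exact permutation with Benjamini-Hochberg adjustment over 16 lists, and by Fisher's exact test over gene end regions. Added after seeing the data, limma 3.58.1 was run in R 4.3.3 on normal scores of the ranks, with treatment as the only term and again with the replicate number as a block, and a gap of at least 20 rank points between groups was counted. Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, with matplotlib 3.10.9 for the figures. Named genes were up to 6 at gene end regions open in one group alone by rank, the 5 with the widest gaps between groups in each direction, the 5 with the highest mean rank, list members not called alike in all libraries with up to 4 examples per list, and RAD21 and CTCF. A region with several genes counts once, and some genes that the rule names are not reported here. The lists covered cohesin and CTCF, colon epithelium, Wnt targets, p53 targets, cell cycle, interferon response, immediate early, DNA repair, ribosomal protein, housekeeping, HOX cluster, clustered protocadherin, blood cell, neuron, hepatocyte, and fibroblast and muscle genes.

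The steps were tested on simulated data. In simulated peak lists of 85328 regions, all 200 regions seeded as lost and all 200 seeded as gained with treatment were recovered. The seeding used the same rule as the search, so this tests only the code. In all, 556 untreated-only and 852 treated-only regions were reported there, so most arose without a seeded change. In simulated rank scores of 45111 regions for 5-Ph-IAA against untreated, limma called 96.5% of 200 regions shifted by 2 score units, 10.5% of 200 shifted by 1 and 1% of 200 shifted by 0.5, with 14 calls among 44511 unshifted regions. With the replicate block it called 69.5%, 1% and 0%. Shifts of about 1 unit or less would thus mostly have been missed. Larger shifts can be missed too, since the simulated noise was independent between libraries and the seeded changes make the adjustment less strict. In the real data, a region of chromosome 1 (147515522 to 147515699) differed by -2.367 and had an adjusted p of 0.231 by limma. Alternatives were a stricter threshold of -log10 q of at least 5, the same number of strongest peaks per library, all sequences, summit windows of 250 bp either side, at least 50% of a region covered, ranks by fold enrichment, gene end windows of 250 bp, the replicate block, and each library left out in turn.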

Results

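Open chromatin was mapped by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into accessible DNA, in HCT116 cells, a human colorectal cancer line. The cells carried the cohesin subunit RAD21 joined to an auxin-inducible degron (mAID) and the fluorescent protein mClover, the plant F-box protein OsTIR1, and the histone variant H3.3 joined to a Halo tag. Cohesin is the ring complex that folds interphase chromatin into loops, many of them anchored at sites bound by CTCF. 5-Ph-IAA is an auxin analog with which OsTIR1 marks degron-tagged proteins for destruction, so that RAD21 is the intended target in treated cells. The labels gave 4 untreated libraries (untreated 1 to 4) and 2 libraries from cells given 5-Ph-IAA (5-Ph-IAA 1 and 2). They named no dose, no duration and no separate cultures, so p-values measure only the spread between these libraries, which may be technical. The amount of RAD21 protein and the read counts behind the peaks were not analysed here.

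The measurements were lists of peaks, called separately in each library, on the human build GRCh38 (hg38). On chromosomes 1 to 22, X and Y, the untreated lists held 63107, 75193, 55695 and 75920 peaks for libraries 1 to 4, and the 5-Ph-IAA lists held 67146 and 77177. Depth could be read only from the peak caller's own values. The background pileup, the number of extended reads over an average position, was 0.52, 0.39, 0.4 and 0.37 in untreated 1 to 4 and 0.48 and 0.43 in 5-Ph-IAA 1 and 2, and the median pileup at a summit was 41, 36, 30 and 30 against 40 and 37. The median fold enrichment of a peak was 16.2, 15.8, 12.8 and 12.9 in the untreated lists and 16.2 and 15.4 in the treated lists, so untreated 3 and 4 had the weakest peaks relative to background.

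The first comparison asked whether the amount and the location of open chromatin differed between untreated cells and cells in which RAD21 was targeted. HCT116 cells given 5-Ph-IAA showed no clear difference from untreated cells in the number or the total length of open places. With 2 against 4 libraries, a difference cannot be excluded. Mean covered length was lower in treated libraries under every alternative, with differences of -2.319 to -0.367 Mb. Untreated 2 nevertheless lay below both 5-Ph-IAA libraries. Promoters and other gene ends, gene bodies and the DNA between genes each held about the same share of peaks in both groups. Of 89455 regions made by merging the 6 lists, 45111, or 50.4%, were open in all 6 libraries, among them the ends of the genes for RAD21, for its partners SMC1A and SMC3 and for CTCF. Among the strongest regions at gene ends were those at MVD and PANK2, which encode enzymes of mevalonate and coenzyme A synthesis, at GCSH, and where ENTPD7 meets SLC25A28, and each had a mean rank of at least 99.9 of 100 in both groups.

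The 5-Ph-IAA libraries had 72162 ± 7093 peaks (SD, n = 2) and the untreated libraries 67479 ± 9810 (SD, n = 4), a difference of 4683 with an exact two-sided permutation p of 0.6. Peaks covered 15.6 ± 0.822 Mb in treated and 17 ± 1.75 Mb in untreated libraries, a difference of -1.46 Mb (exact permutation p = 0.4, n = 2 and 4). Without untreated 3 and 4, the differences were 3012 peaks and -0.367 Mb. There are only 15 ways to split 6 libraries into groups of 2 and 4, so that no test of this kind could give a p below 0.0667. Leaving out 5-Ph-IAA 2 turned the difference in peak number to -332.8.

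**Figure D1:**
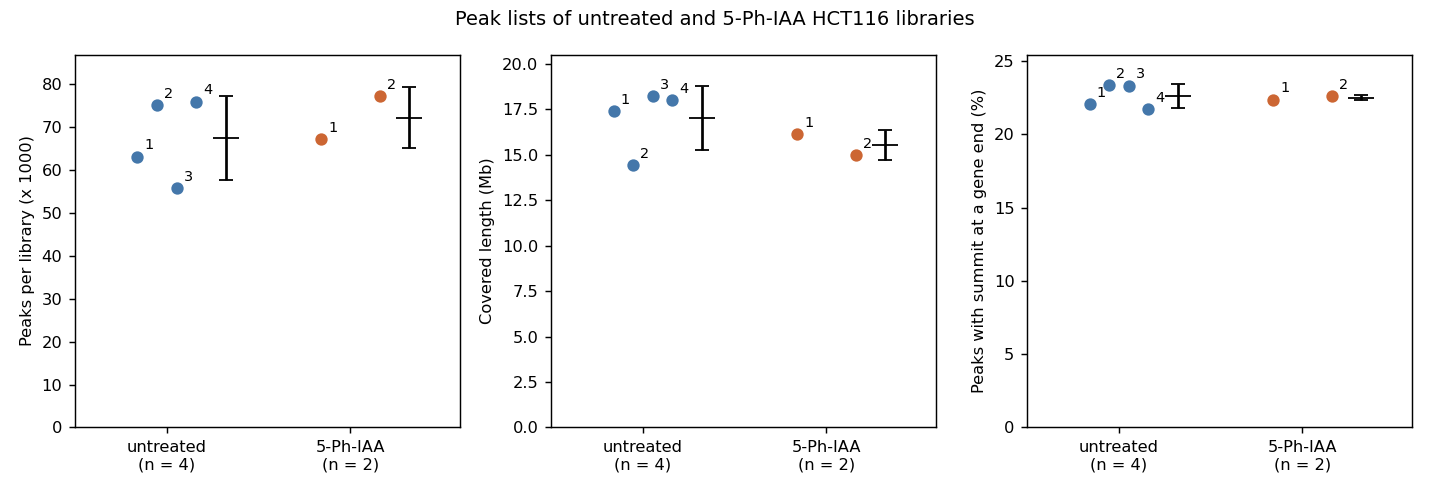
Peaks per library (axis in units of 1000 peaks), covered length in megabases and percent of peaks with the summit within 1000 bp of a gene end, with a point for each library (numbers as in the labels) and a bar for the group mean and SD. The untreated libraries range from 55695 to 75920 peaks, and both 5-Ph-IAA libraries, at 67146 and 77177, overlap or lie next to that range.

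Gene ends, taken as 1000 bp either side of the outermost annotated bases of each protein-coding gene, held the summits of 22.5% ± 0.165 of peaks (SD, n = 2) in 5-Ph-IAA libraries and 22.6% ± 0.848 (SD, n = 4) in untreated libraries. That difference of -0.126 percentage points had an exact permutation p of 0.867 with n = 2 and 4. It was 0.719 with the same number of strongest peaks in every library, 0.119 without untreated 2 and 0.109 without untreated 3. Gene bodies held 41.2% ± 0.225 of treated and 40.9% ± 0.602 of untreated peaks (exact permutation p = 0.667, n = 2 and 4), and the DNA outside genes held 36.3% ± 0.39 and 36.5% ± 0.614 (exact permutation p = 0.8). The share of peaks on each chromosome was also compared by exact permutation, although no chromosome could pass with 15 splits. The lowest p was that of chromosome 9, with 4.35% ± 0.044 of treated and 4.25% ± 0.035 of untreated peaks (exact permutation p = 0.0667, n = 2 and 4).

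The libraries most alike were not those of a shared treatment. The bases open in untreated 2 overlapped best with those open in 5-Ph-IAA 2, and those of untreated 1 with those of 5-Ph-IAA 1. The Jaccard index, shared bases over all covered bases, was 0.78 and 0.76 for those pairs, 0.731 for the treated pair and 0.656 for untreated 1 and 2. It averaged 0.651 within the untreated group and 0.681 between the groups. Mean overlap within groups minus mean overlap between groups was -0.0187, and 10 of the 15 splits gave a contrast at least as large in size (exact two-sided permutation p = 0.667). Leaving out untreated 2 turned this contrast to 0.0421, and without untreated 3 and 4 it was -0.0337. Across the regions open in all 6 libraries, which are not independent replicates, Spearman's rho of the ranks was 0.958 for untreated 2 with 5-Ph-IAA 2, 0.941 for untreated 1 with 5-Ph-IAA 1 and 0.937 for the treated pair. It was 0.898 for untreated 1 with 2, 0.869 for untreated 3 with 4 and 0.784 for untreated 2 with 4.

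**Figure D2:**
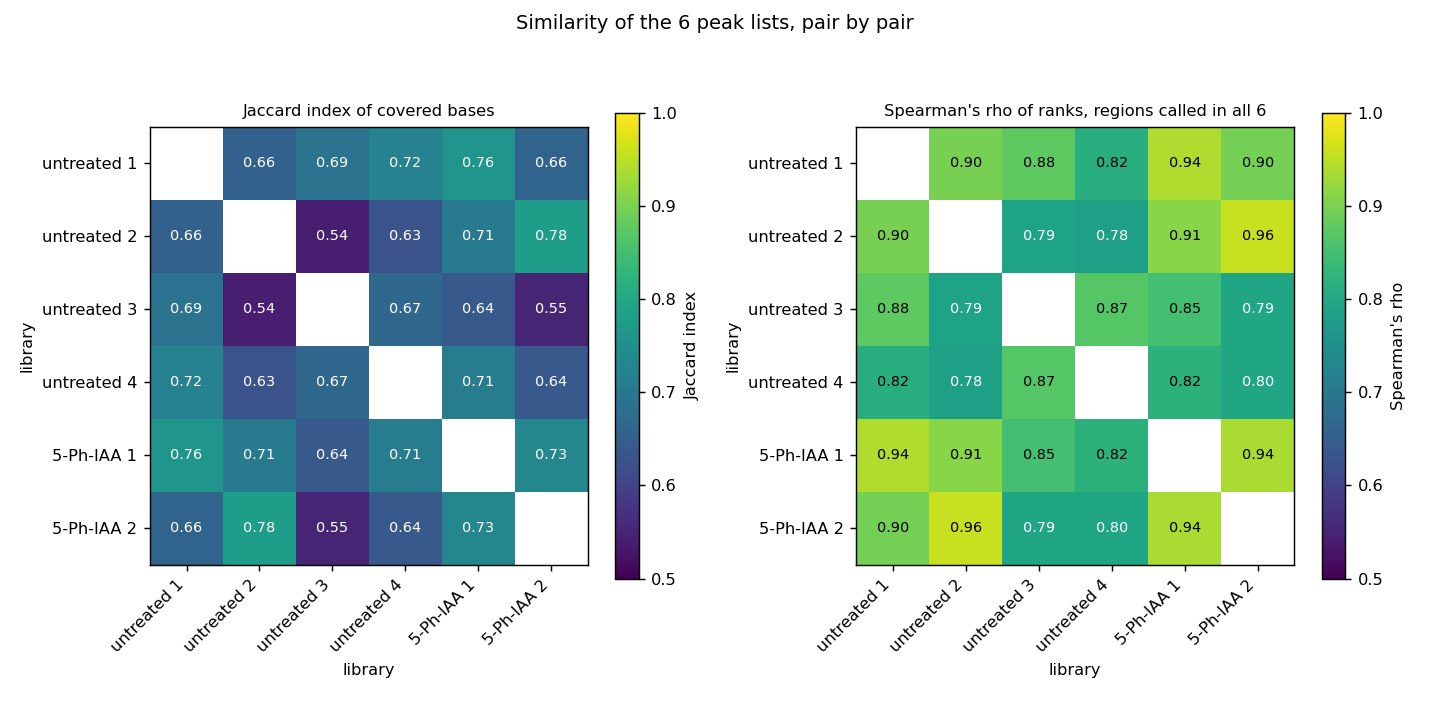
Jaccard index of covered bases and Spearman's rho of ranks over the 45111 regions called in all 6 libraries, for each pair of libraries, both without units and on a colour scale from 0.5 to 1. Untreated 2 with 5-Ph-IAA 2 gives the highest value in both panels, 0.78 and 0.958, and untreated 3 and 4 have lower values with untreated 2 and 5-Ph-IAA 2.

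The second comparison asked which genes had open chromatin at an end in each group. Genes of cohesin, the cell cycle and DNA repair were open in untreated and in treated cells alike. A peak lay at an end of all 15 genes of cohesin and its regulators with CTCF, all 19 cell cycle genes and all 14 DNA repair genes in each of the 6 libraries. Markers of blood, liver, muscle and connective tissue were mostly without a peak in both groups. The gene of a fibrous collagen chain, COL1A2, was the only listed gene with a peak in all 4 untreated and neither 5-Ph-IAA library.

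Among 20037 protein-coding genes, 12596 ± 86.3 had a peak at an end in treated libraries (SD, n = 2) and 12530 ± 167 in untreated libraries (SD, n = 4; exact permutation p = 0.667), and 12023 had one in all 6. Only 8 genes had a peak at an end in every untreated and no treated library, and 9 the reverse. Other splits of the libraries gave up to 49 and 44 such genes.

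The list of cohesin, its loaders and release factors, and CTCF had all its members open in both groups. The region at the RAD21 end (chromosome 8, 116874175 to 116875080) had a mean rank of 75.7 ± 18.8 of 100 in untreated (SD, n = 4) and 56.5 ± 2.5 in treated libraries (SD, n = 2; exact permutation p = 0.267), and a fold enrichment of 19.7 and 19.6. At the CTCF end (chromosome 16, 67561859 to 67562587) the mean ranks were 91.5 ± 10.6 and 97.6 ± 0.1 (exact permutation p = 0.733, n = 4 and 2). The means at the RAD21 end thus differed by more than either SD. SMC3 (84.8 ± 4.4 and 83.9 ± 1.8) and the release factor WAPL (94.7 ± 2.2 and 93.8 ± 0.9) had the same place in both groups to within their SD (n = 4 and 2).

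Of the 24 colon epithelium genes, 14 had a peak at an end in each untreated library and 13 and 14 in the treated libraries. EPCAM and CDH1, which encode adhesion proteins of epithelial cells, and CDX2, an intestinal transcription factor, were open in all 6, whereas KRT20 and MUC2, markers of differentiated colon cells, had no peak in any. The receptor gene EPHB2, also counted among Wnt targets, lacked a peak in 5-Ph-IAA 1 alone. Of the 15 Wnt targets, 13 were open in each untreated library and 12 and 13 in the treated libraries, with AXIN2, an inhibitor of the pathway, at ranks of 65.7 ± 13.6 (SD, n = 4) and 60.4 ± 11.9 (SD, n = 2). The 15 p53 targets gave 13 in every library, the 12 immediate early genes 10, and the 16 ribosomal protein genes 14. MDM2, the ubiquitin ligase of p53, ranked 68.3 ± 11.2 in untreated (SD, n = 4) and 60.9 ± 7.8 in treated libraries (SD, n = 2), and FOS, an AP-1 gene, 61.1 ± 8.9 and 68.2 ± 3. Interferon response genes were open in 12, 12, 11 and 11 of 15 cases in untreated 1 to 4 and in 12 and 12 in the treated libraries. IFIT2 lacked a peak in untreated 3 and IRF7 in untreated 4. Housekeeping genes gave 10, 11, 10 and 10 of 12 in untreated libraries and 10 and 11 in treated ones, with B2M, the light chain of class I molecules, open only in untreated 2 and 5-Ph-IAA 2.

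HOX cluster genes, whose products set body position, were open in 23, 25, 23 and 25 of 39 cases in untreated 1 to 4 and in 23 and 25 in treated libraries. Clustered protocadherin genes, which encode adhesion proteins of neurons and are regulated through cohesin and CTCF, were open in 26, 25, 4 and 25 of 52 cases in untreated 1 to 4 and in 24 and 24 in treated libraries. The 21 gamma genes missing in untreated 3 end at the same base of chromosome 5, 141512975, so that a single region (141512441 to 141512622) decided them, and without untreated 3 the difference between group means turned from 4 to -1.333. Among lists of other cell types, blood markers gave 3 of 12 in every library, neuron markers 5, 7, 6 and 6 of 12 in untreated and 7 and 6 in treated libraries, and hepatocyte markers 2, 2, 3 and 3 of 10 in untreated and 3 and 2 in treated libraries. Fibroblast and muscle markers gave 5 of 12 in each untreated and 4 in each treated library, the difference being COL1A2 (exact permutation p = 0.0667, the smallest this design allows, and 1 after adjustment over the 16 lists). With windows of 250 bp at gene ends, each group had a mean of 1 and the difference was 0. The adjusted p was 1 for the other lists too. By limma, none of the 166 list regions open in all 6 libraries passed when adjusted over the list alone or over all 45111 regions. A region in several lists, such as that of LGR5, was counted once in each. By limma, 3 of the 166 had an unadjusted p under 0.05, a smaller share than chance gives at 0.05. Among them were HOXD11 with a score difference of 0.901 and PCDHGA10 with -0.681. In Fisher's exact test over gene end regions, no list was enriched among regions that ranked higher or lower in treated libraries, with an adjusted p of 1 for every list.

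These counts depend on the annotation used. The table of genes gave the outermost bases without strand, so that open sites inside a gene were not counted: CDKN1A, a p53 target, was without a peak at either end in every library and had 3 or 4 peaks inside the gene in each. TUBB and IER3 lie between 29 and 33 Mb of chromosome 6, where all 6 lists were empty.

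The third comparison asked which regions were open in one group alone. A small set of places, mostly away from gene ends, was called in every untreated library and in neither 5-Ph-IAA library, and another in both treated libraries alone. The strongest at genes in untreated libraries alone lay at HOGA1, which encodes an enzyme of hydroxyproline breakdown, TMEM270, CFAP144 and COL1A2. Next were PRICKLE1, a planar cell polarity gene, and GALNT6, an enzyme of O-glycosylation. Those in treated libraries alone lay at MCRS1, TGFBI, which encodes a secreted matrix protein induced by TGF-beta, TATDN2 and CLEC17A. Next were MKI67, the proliferation marker, and a region shared by C20orf141 and TMEM239.

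In all, 371 regions were called in every untreated and no treated library, and 620 in every treated and no untreated library. Other splits of the same libraries gave between 38 and 1884 and between 72 and 2426 such regions, and 6 and 5 of the 15 splits gave at least as many as the real one. Setting untreated 2 and 5-Ph-IAA 2 against the other 4 libraries gave 818 and 2426. Without untreated 3 and 4, the numbers were 1107 and 1469. Leaving out a single library gave 446 to 1122 untreated-only and 689 to 4240 treated-only regions, with 1122 and 2092 without untreated 2 and 852 and 4240 without 5-Ph-IAA 1.

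The untreated-only region near HOGA1 (chromosome 10, 97612492 to 97612740) had a fold enrichment of 13.5 to 22.4 and a mean rank of 42.8 of 100 within the lists. That at COL1A2 (chromosome 7, 94395542 to 94395678), within the annotated gene, had 9.2 to 15 and a mean rank of 28.8. The treated-only region at TGFBI (chromosome 5, 136028869 to 136029018) had a fold enrichment of 13.5 to 13.9 and a mean rank of 31.5, and that at MCRS1 (chromosome 12, 49568931 to 49569066) 10.5 to 12.7 and 35.4. MKI67 had its main end region (chromosome 10, 128126187 to 128126845) open in all 6 libraries, with ranks of 93.7 ± 6.7 in untreated (SD, n = 4) and 83.9 ± 1.2 in treated libraries (SD, n = 2; exact permutation p = 0.133). The treated-only peak (128126935 to 128127037) lay beside it with a fold enrichment of 6.8. Regions open in one group alone were weak: the median of their lowest -log10 q was 10.2 for untreated-only and 10.7 for treated-only regions, against 31.1 for regions open in all 6.

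Gene ends made up 5.93% of the untreated-only and 4.03% of the treated-only regions, against 8.22% of all regions called in 1 to 5 libraries and 26.2% of those called in all 6. Fisher's exact test over regions, which are not independent replicates, gave an odds ratio of 0.702 (p = 0.128) for untreated-only and 0.466 (p = 4.56e-05) for treated-only regions against the others called in 1 to 5 libraries. For untreated 2 and 5-Ph-IAA 2 as a pair, the share at gene ends was 5.5% and 7.25%. Over the other splits, the share ran from 5.5% to 13.16% for regions called only in the larger group. For those called only in the pair, it ran from 4.71% to 12.5%. The untreated-only share thus lay within the range of other splits and the treated-only share below it. Away from gene ends and chosen after their values were seen, the strongest untreated-only regions included those inside KANK1 (chromosome 9, 613846 to 614116), GABRP (chromosome 5, 170809642 to 170809851) and HEG1 (chromosome 3, 124995538 to 124995695), with fold enrichments of 17.7 to 26.4, 16.7 to 28.5 and 15 to 23.5. Treated-only regions included those inside ACTR3C (chromosome 7, 150283721 to 150283832) and BICD1 (chromosome 12, 32290515 to 32290650), with 16.2 to 18.8 and 14.8 to 16.7.

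**Figure D3:**
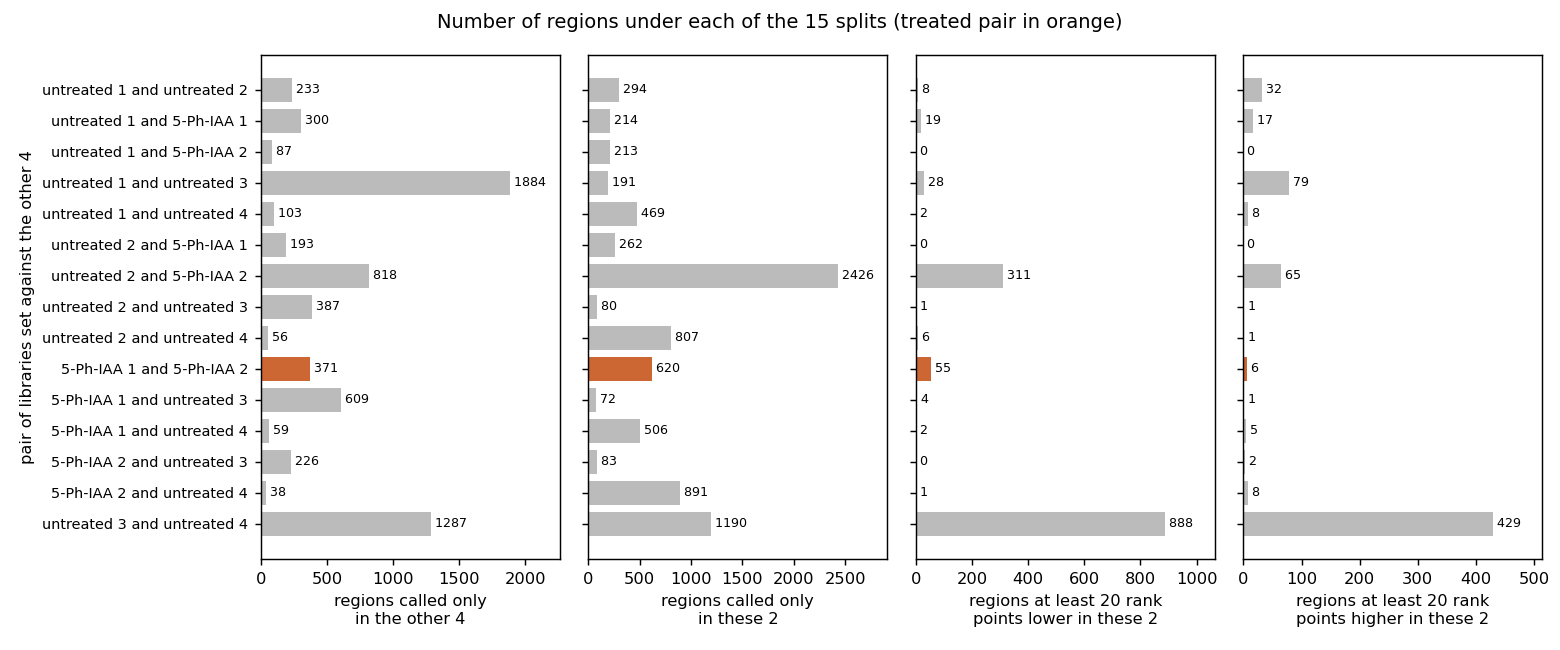
Number of regions for each of the 15 ways to set 2 libraries against the other 4, from left to right called only in the 4, called only in the 2, at least 20 rank points lower in the 2 and at least 20 higher. The treated pair, in orange, has 371, 620, 55 and 6 regions, and other pairs, in grey, reach 1884, 2426, 888 and 429.

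The last comparison asked whether regions open in all libraries became more or less prominent with 5-Ph-IAA, judged by each region's rank within its own library. One region, at an end of PI16, a gene for a secreted peptidase inhibitor, was lower in treated cells by limma. It had a fold enrichment of 19.5, 18.8, 10.2 and 14.1 in untreated 1 to 4 and of 5.65 and 5.67 in 5-Ph-IAA 1 and 2. Ends of KISS1R, the kisspeptin receptor gene, NWD1, KRT13, a keratin gene, and DAGLA, a lipase gene, also had lower ranks in both treated libraries, and those of HTD2 and RPP14, ZNF565, CCDC88B and RPS6KA4, TBC1D10C and BNIP2 had higher ones, without passing a test. Most regions with wide gaps between the groups were on the lower side and lay away from gene ends.

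The PI16 region (chromosome 6, 36948035 to 36948364) lay at places 5 and 15 from the bottom of the 45111 ranked regions in 5-Ph-IAA 1 and 2, and at percentiles of 46.2, 36, 18.3 and 24.5 in untreated 1 to 4. By limma on normal scores of the ranks, its score differed by -3.054 ± 0.282 (SE, n = 2 and 4), with an adjusted p of 0.0384, or 0.197 with numbers 1 and 2 as a replicate block. It was the only one of 45111 regions that passed, at 0 higher and 1 lower. An unadjusted limma p under 0.05 was found in 1606 regions, 481 higher and 1125 lower. That is a smaller share than chance gives at 0.05, and other splits gave 347 to 13205 such regions. Without untreated 3 and 4 limma called 0 regions, and without untreated 2 it called 2, both lower. Among the single libraries left out, the call was also lost without untreated 1, 3 or 4. Without either treated library, the lone treated library is assumed to vary like the untreated ones, so that the 0 calls found there were not counted as a loss. The same fit with untreated 3 and 4 set against the rest called 1221 regions higher and 2365 lower.

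Both treated ranks lay below all untreated ranks in 2619 regions, 5.81% of 45111, and above them in 2728, or 6.05%. Chance alone gives 6.67% in each direction, or 3007 regions, and other splits gave from 1071 to 9343 lower and from 1271 to 8047 higher. Regions ranking higher in treated libraries were at gene ends in 18.8%, against 26.7% of the rest (Fisher's exact test, odds ratio 0.635, p = 5.8e-21). Those ranking lower were at gene ends in 25.4% (Fisher's exact test, odds ratio 0.954, p = 0.314). Both tests count regions, which are not independent replicates, and these shares were not computed for other splits. The shares can thus not be tied to treatment.

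A gap of at least 20 rank points, chosen after the data were seen, separated the groups in 55 regions with lower and 6 with higher treated ranks. Other splits gave 0 to 888 and 0 to 429, and without untreated 3 and 4 the numbers were 229 and 48. Without untreated 2 they were 185 and 111, and ranking by fold enrichment gave 85 and 15. Of the 55 regions, 1 lay at a gene end, or 1.82% against 26.2% of the rest, while 41.8% lay inside genes and 56.4% outside. Fisher's exact test over regions, which are not independent replicates, gave an odds ratio of 0.0521 (p = 1.67e-06). Among other splits, the 4 with the most regions past this gap on the lower side had 14.1% (888 regions, untreated 3 and 4), 4.5% (311, untreated 2 and 5-Ph-IAA 2), 10.7% (28, untreated 1 and 3) and 52.6% (19, untreated 1 and 5-Ph-IAA 1) of them at gene ends.

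At gene ends, the DAGLA region (chromosome 11, 61680081 to 61680532) ranked 56.2 ± 11.9 in untreated (SD, n = 4) and 21.3 ± 10.8 in treated libraries (SD, n = 2; exact permutation p = 0.0667), and the KISS1R region (chromosome 19, 917415 to 918035) 35.4 ± 8.9 and 4 ± 1.1. The NWD1 region (chromosome 19, 16719696 to 16719979) ranked 30.9 ± 6.7 and 4.6 ± 0, and the KRT13 region (chromosome 17, 41500097 to 41500392) 71.4 ± 7.7 and 44 ± 3.7. On the higher side, the region shared by HTD2 and RPP14 (chromosome 3, 58307076 to 58307267) ranked 6.8 ± 4.4 in untreated (SD, n = 4) and 29 ± 0.6 in treated libraries (SD, n = 2), TBC1D10C (chromosome 11, 67410143 to 67410339) 16 ± 9.8 and 44 ± 6, and BNIP2 (chromosome 15, 59689895 to 59690058) 15.8 ± 8.1 and 35.4 ± 1.1. The ZNF565 region (chromosome 19, 36182605 to 36183069) and that of CCDC88B and RPS6KA4 (chromosome 11, 64357955 to 64358484) both differed by 28.5 points. A region just beyond the upper end of the MYC oncogene (chromosome 8, 127743050 to 127743269) ranked 54.2 ± 17.3 in untreated (SD, n = 4) and 65.9 ± 4.3 in treated libraries (SD, n = 2; exact permutation p = 0.533). That at the lower end of CCND1, the cyclin D1 gene (chromosome 11, 69640941 to 69641280), ranked 26.1 ± 13.3 and 48.8 ± 15.3 (exact permutation p = 0.2). Both were picked from the Wnt targets, of which others ranked lower in treated libraries. ZNRF3 was among those, at 56.7 ± 3.6 in untreated (SD, n = 4) and 34.7 ± 19.2 in treated libraries (SD, n = 2; exact permutation p = 0.0667).

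Away from gene ends, and named after their values were seen, the widest gap was in a region 52342 bp from BTRC (chromosome 10, 101301517 to 101301706), which ranked 63.1 ± 12 in untreated (SD, n = 4) and 5.2 ± 0.6 in treated libraries (SD, n = 2; exact permutation p = 0.0667; limma adjusted p = 0.266). Regions inside COL17A1, a hemidesmosome collagen gene (chromosome 10, 104045528 to 104045699), VXN (chromosome 8, 66512294 to 66512625) and SLC26A5 (chromosome 7, 103406924 to 103407174) ranked 77.6 ± 8.3, 60.1 ± 10.1 and 52.9 ± 8.2 in untreated (SD, n = 4) and 30.5 ± 0.2, 13.5 ± 1 and 9.3 ± 1.9 in treated libraries (SD, n = 2). The widest gap in the other direction was inside CCND1 (chromosome 11, 69644242 to 69644791), at 15.7 ± 16.5 in untreated (SD, n = 4) and 65.6 ± 7 in treated libraries (SD, n = 2; exact permutation p = 0.0667). Its fold enrichment was between 3 and 12.7 over the 6 libraries.

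**Figure D4:**
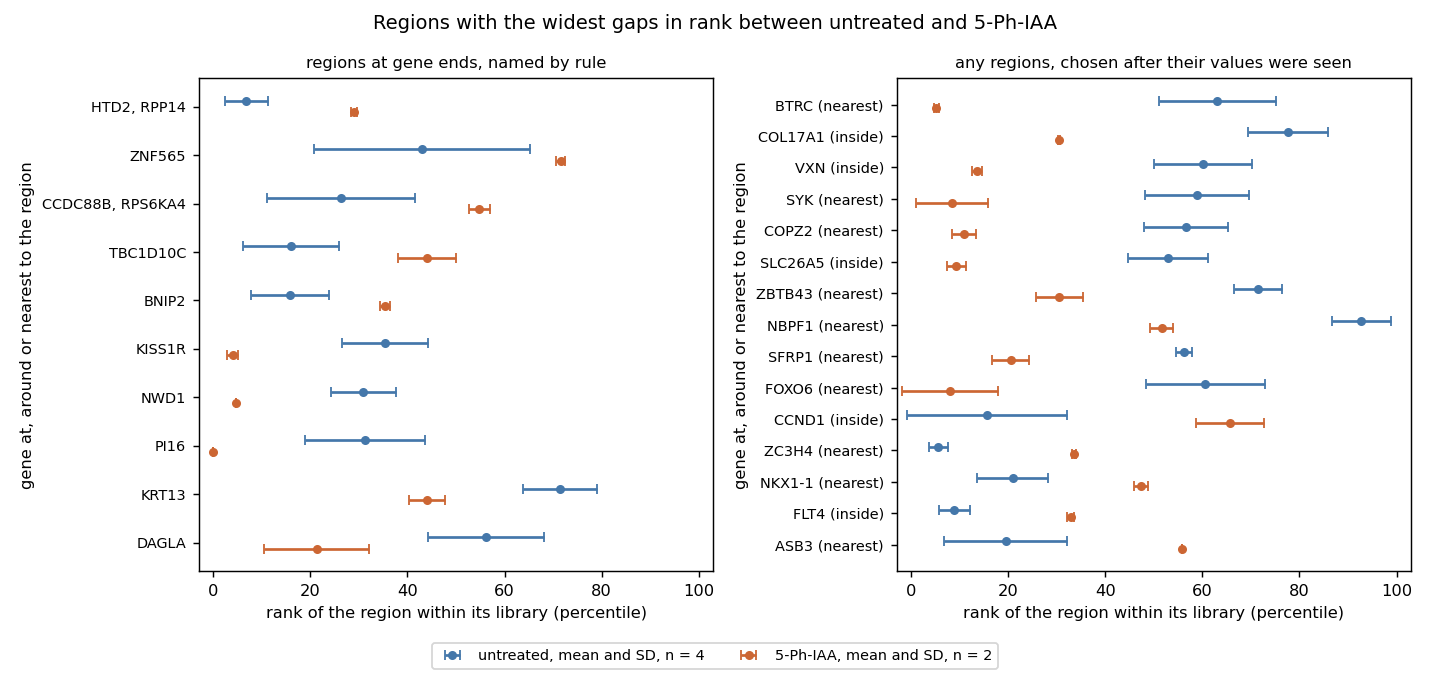
Rank of each region within its library, in percentiles over the 45111 regions called in all 6 libraries, as group mean with SD for untreated (n = 4) and 5-Ph-IAA (n = 2), for regions at gene ends named by a fixed rule on the left and for regions chosen after their values were seen on the right. PI16 lies near 0 in treated libraries and at 31.2 ± 12.4 in untreated libraries, and the CCND1 region lies at 65.6 and 15.7.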

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

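The tests of explanations in this part were chosen after the results were seen. Among 21 quantities with any spread between the 4 untreated libraries, 2 had a library far from the other 3, and chance alone would give about 1 in 20. The number of housekeeping genes with a peak at an end was 10, 11, 10 and 10 in untreated 1 to 4, where B2M in untreated 2 made up the whole range, a ratio of 1. The other was the number of clustered protocadherin genes with a peak at an end, 26, 25, 4 and 25 in untreated 1 to 4, where the gap between untreated 3 and the nearest library made up 0.955 of the whole range. A single region behind 21 gamma genes, with a fold enrichment of 10.8 to 15.5 in the other 5 libraries, accounts for 21 of the missing genes, so the value stands for 1 region and not for the gene family.

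Untreated 3 and 4 also stood apart from the other 4 libraries, in a way that no label names. By limma they differed from the rest in 3586 of 45111 regions, against 1 for treatment and 0 for each of the other splits, which points to a structure of the samples. Depth or fragment length stays open: they had the lowest depth indices, 4.04 and 5 against 5.27 to 5.81, and the lowest median summit pileups, 30 and 30 against 36 to 41, while Spearman's rho of untreated 4 with untreated 3 exceeded that with untreated 2, which has the same smallest peak width, by 0.0849, a value of a single library that excludes nothing. By rho, untreated 4 was nearest to untreated 3 (0.869), but untreated 3 was nearer to untreated 1 (0.876). By the Jaccard index, untreated 3 and 4 were each nearer to untreated 1 (0.69 and 0.721) than to each other (0.67). Untreated 4 was also nearer to 5-Ph-IAA 1 (0.713). Weaker enrichment over background stays open too, with a median fold of 12.8 and 12.9 against at least 15.4 in the others. So does a separate preparation, since the labels name no batch. A value from the peak lists also set the 2 apart. Summit pileup and background could be recovered for 99.99% of peaks in each, against 97.03% to 97.4% in the others. It marks them as a pair but cannot tell a separate preparation from separate processing. Both libraries are untreated, so no biological explanation was tested.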

How the results depend on the processing

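The limma fits, the 20 point gap the runs without both untreated 3 and 4 and the gene list runs without 1 library were chosen after seeing the data; the other alternatives were planned. No permutation test can pass 0.05 here, so stability means direction or size. Over the alternatives, 77 values kept their direction, or stayed within 1.5 times for counts, 44 moved further and 5 reversed, and of the gene list differences 39 kept their direction, 3 reversed, 7 became 0, 48 stayed at 0 and 15 moved from 0. The 44 are not all separate: the run without untreated 3 and 4 repeats values of the replicate block run. They also include limma calls set against counts of regions whose ranks do not overlap, which are unlike measures. Causes of the moves and reversals were not tested. Fewer libraries set fewer conditions, which can raise the counts, but the size also changed with the library left out. On the libraries numbered 1 and 2 alone (replicate block; also the run without untreated 3 and 4), fewer conditions left 1107 untreated-only and 1469 treated-only regions, 7541 ranked higher and 7327 lower, and 229 and 48 past the gap. Limma called 0 higher and 1 lower, and 0 and 0 with the replicate block (664 and 1115 at an unadjusted p under 0.05). These shared numbers are no stated pairing: deviations from the group means correlated at 0.22 for number 1 and 0.468 for number 2. With at least 50% of a region covered, 28 and 3 regions passed the gap, and 85 and 15 by fold enrichment. The gene end share reversed to 0.719 with equal peak numbers, and the protocadherin difference to -0.75 with 250 bp windows, where the fibroblast and muscle difference became 0. Leaving out 1 library gave peak number differences of -332.8 (without 5-Ph-IAA 2) to 9698, covered length of -2.319 to -0.879 Mb, overlap contrasts of -0.0531 to 0.0421, gene end share differences of -0.43 to 0.119 (0.109 without untreated 3), untreated-only regions of 446 to 1122, treated-only of 689 to 4240, ranked higher 3947 to 7911, lower 3731 to 7147, gaps lower 81 to 185 and higher 9 to 111, the protocadherin difference of -1.333 (without untreated 3) to 6 and the housekeeping difference of -0.25 (without 5-Ph-IAA 2) to 0.75. CTCF motif alternatives and the start site alternative were not run, for want of a genome sequence and strands. What depth limits was not tested.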

Other observations

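The tests of explanations for the chromosome 6 stretch in this part were chosen after the result was seen, and those for the rank gaps after the gap was seen but before the values they measure. Between 29 and 33 Mb of chromosome 6, the stretch that holds the major histocompatibility complex with its HLA genes, none of the 6 libraries had a peak, and none of its 144 protein-coding genes had one at an end, against 64.9% of all 20037. The 25 to 28 Mb stretch beside it held 184 to 247 peaks per library. TUBB, a tubulin gene that dividing cells need, lies in the empty stretch. Among 654 windows of 1 Mb with at least 10 protein-coding genes, others without any peak included one at 93 to 94 Mb of chromosome 14, and windows at 55 Mb of chromosome 11 and 30 Mb of chromosome 21. A candidate explanation is that reads of this stretch match alternate haplotype sequences of the build as well and were removed as ambiguous. Every library had peaks on alternate sequences of chromosome 6, from 38 to 47 of them on 6 sequences, as this explanation predicted. Which part of chromosome 6 these sequences stand for was not checked, so the test cannot tell it from a loss of the stretch from the cells. Nor does it speak for a particular filter, which is not given in the sources used here.

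Regions at least 20 rank points lower in both treated libraries were few and nearly all away from gene ends, and both treatment and differences between libraries may account for them. Among regions called in all 6 libraries, 178 were chosen by the ranks in the libraries numbered 1 and 2. Untreated 3 and 4 thus had a part in the choice through their calls. In these regions they lay at a median position of 0.594 between the treated mean (0) and the untreated mean (1). The bootstrap interval of 0.512 to 0.686 fell between the bounds set in advance. It resampled regions, which are not independent replicates, so it does not measure the spread between libraries. The same choice with untreated 1 and 5-Ph-IAA 1 as the lower pair gave 209 regions and a position of 0.26, and with untreated 2 and 5-Ph-IAA 2 gave 597 regions and 1.029. With the groups reversed, so that untreated 1 and 2 were the lower pair, 25 regions gave a position of 0.537. Peak width was tested on 354 regions, also from those called in all 6 libraries. They were chosen by ranks without untreated 2 and 5-Ph-IAA 2, which share a smallest width of 74 bp. Untreated 2 ranked 10.21 points above 5-Ph-IAA 2 in the median and above it in 80.2% of regions. The bootstrap interval over regions, 8.01 to 11.78, lay around the bound set in advance. A lower rank of these distal regions after 5-Ph-IAA is therefore a hypothesis that these 6 libraries leave open, and treatment and library differences cannot be told apart for them.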
